A study of Marchantia polymorpha and Klebsormidium nitens with 125 samples.

How the data were processed

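RNA was sequenced from whole gemmalings of the liverwort Marchantia polymorpha and from cultures of the filamentous streptophyte alga Klebsormidium nitens. Gemmalings are young plants grown from gemmae, the asexual propagules of the liverwort. Per the labels' protocols, both organisms were grown for 7 days in liquid Yamagami medium and were then moved for 5 days to medium with 1% of the nitrate, 1% of the phosphate or 0% of the sucrose. Full medium was then given back for 6, 24 or 72 h. The protocol describes this replacement for M. polymorpha, and the labels list resupplied libraries for K. nitens as well. Wild-type plants were of the strain Tak-1. Knock-out mutants of MpCSD, MpERF20 and MpHD9 (Mpcsd-2, Mperf20-21 and Mphd9-14) were studied under control conditions and after each starvation. Libraries were directional and enriched for polyadenylated RNA.

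The deposited values were whole-number counts per gene and library, in 4 tables, 1 for each set of libraries. Reads were aligned with STAR 2.7, and DESeq2 was among the tools, per the submitters' processing notes. The genome builds, the annotation, the counting program and its strand setting were not given in the sources used here, so reads shared by near-identical family members or by overlapping antisense genes could have been split in a way that is unknown. All tests started from the counts as the authors deposited them. The tables held 16122 genes for K. nitens and 19355 for M. polymorpha. They included 74 tRNA and rRNA genes of K. nitens, which took at most 0.0395% of a library. No columns were left unmatched (0), and 0 pairs of libraries held identical counts. For K. nitens, 24 columns matched a group but no single sample and were used as its replicates without their numbers.

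Totals per library ran from 16878159 to 38992957 counts. A count of 0 in a group was read as at most 3 counts over the group. Ratios against a group with 1 to 3 counts are given with a 95% exact interval from the binomial split of the counts, which covers counting error only. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

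Gene symbols of M. polymorpha were taken from a reference table of assembly MpTak2_v7.1, used for names alone; 17384 of the 19355 identifiers matched and 3091 had a symbol. No coordinates were used, because the build behind the counts was not given. For K. nitens no table paired identifiers with names.

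Each table was fitted once with edgeR 4.0.16 (limma 3.58.1, R 4.3.3), using TMM scaling, the expression filter filterByExpr with the groups, and the quasi-likelihood F-test on contrasts of group means, two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Starved groups were compared with the control group, resupplied groups with the starved group of the same nutrient, and groups at 72 h of resupply with the control group. Mutants were compared with Tak-1 under control conditions, and starved mutants with their own control. The response of each mutant was compared with that of Tak-1 by an interaction contrast, fitted over the mutant libraries and the Tak-1 libraries of the time course, which came from different tables and experiments. Fold changes are on the log2 scale with their standard error (SE), and levels are counts scaled to the library size (CPM) as mean ± SD over replicates.

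Gene lists were tested with camera on voom values, with its preset correlation of 0.01 between genes, with an estimated correlation, and with fry. Adjustment was over the lists of a comparison. Of 21 lists set by words before the data were examined, 14 matched no M. polymorpha symbol and 7 matched genes. A further 37 lists of family symbols were written after the table of names was opened and before any test was run. Lists with at least 5 measured members were tested, 42 of them in the starvation comparisons. Genes are named by a rule fixed at the same time as the word lists. It takes, among called genes with a symbol, a mean of at least 10 CPM in the higher group and replicates that do not overlap, the 5 with the highest and the 5 with the lowest fold change. It adds up to 3 members of each list with the smallest adjusted p, the genes MpCSD, MpERF20 and MpHD9, and, in later comparisons, the genes named for starvation of the same nutrient. Fewer were named where space required it.

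The calling steps were tested on simulated counts with few genes changed by known amounts, fewer than most comparisons called. For nitrate in M. polymorpha, 85.1% of 67 genes changed 2-fold were called and 3.73% of 161 calls were false, with 13147 of 13344 unchanged. For nitrate in Mpcsd-2 these shares were 85.1% of 67 and 1.95% of 154 (12908 genes). For its interaction with wild type they were 70.8% of 65 and 5.15% of 136 (13189). The false shares were 6.84% for Mpcsd-2 against Tak-1 (190 calls), 6.18% for nitrate in K. nitens (178) and 5.52% for sucrose in Mperf20-21 (163).

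The alternatives tried were DESeq2 1.42.0 in place of edgeR, median-ratio size factors in place of TMM, no expression filter, a filter of 5 CPM in 3 libraries, a replicate block, a fit of the compared groups alone, and leaving out each library in turn. For the interactions a fit of their 4 groups alone was added after the data were seen, as were list tests of phosphate starvation without starved replicate 2. Splits of the libraries were run in fits of the compared groups alone. Overlaps between comparisons that share control libraries are given with the overlap of independent lists and with simulated unchanged groups. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.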

Results

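The series held 125 libraries in 42 groups, with 3 libraries in each group except the sucrose-starved Mperf20-21 group, which had 2. The M. polymorpha time course and the K. nitens time course each had 39 libraries in 13 groups: control, starved of nitrate, phosphate or sucrose, and resupplied for 6, 24 or 72 h after each starvation. A set of 12 libraries compared the 3 mutants and Tak-1 under control conditions, and a set of 35 libraries held each mutant under control conditions and after each starvation. Totals per library ran from 19930892 to 38992957 counts in the M. polymorpha time course and from 18750994 to 33047350 in K. nitens. They ran from 20161746 to 27511775 in the control-condition set and from 16878159 to 28439838 in the mutant starvation set. The design asks how the transcriptional response to nutrients compares between an alga and a land plant, and what 3 transcription factors contribute to it in the liverwort. Changes below are log2 fold changes ± SE with edgeR's adjusted p, and levels are mean ± SD with n = 3 unless another n is given.

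Nitrate starvation of wild-type M. polymorpha raised MpWRKY14, MpNLA and a pair of polyphenol oxidases, and lowered MpExpansin32 and MpFRO2. MpWRKY14 (Mp6g16800), of a transcription factor family known from defence, rose by 2.33 ± 0.46 (adjusted p = 0.000251), from 2.42 ± 0.432 to 12.2 ± 11.3 CPM. The polyphenol oxidases MpPPO4 (Mp2g05810) and MpPPO2 (Mp2g05780) rose by 2.04 ± 0.27 (adjusted p = 9.57e-07) and 1.96 ± 0.37 (adjusted p = 0.000143). MpNLA (Mp4g03460), named after the nitrogen limitation adaptation gene of Arabidopsis, rose by 1.92 ± 0.27, from 4.01 ± 0.585 to 15.2 ± 1.05 CPM (adjusted p = 2.53e-06). MpExpansin32 (Mp4g06560), an expansin, a class of proteins that loosen cell walls, fell by 2.08 ± 0.17, from 115 ± 5.23 to 27 ± 4.62 CPM (adjusted p = 3.66e-10). The ferric reductase MpFRO2 (Mp3g20260) fell by 2.06 ± 0.18, from 20.2 ± 3.7 to 4.85 ± 0.478 CPM (adjusted p = 9.97e-10). MpCupin83 (Mp5g13860) fell by 2.74 ± 0.55 (adjusted p = 0.000273) and the dioxygenase MpDOXC28 (Mp5g00520) fell by 1.63 ± 0.15 (adjusted p = 2.82e-09). In each of these genes the starved libraries did not overlap with the control libraries.

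More WRKY and ERF genes rose than fell under nitrate starvation. Of 13 measured WRKY genes 10 rose and 0 fell, among them MpWRKY10 (1.17 ± 0.12, adjusted p = 1.36e-08) and MpWRKY9 (0.84 ± 0.12, adjusted p = 1.77e-06). The family ranked higher than other genes by camera (adjusted p = 1.91e-05), and adjusted p = 0.149 with an estimated correlation. Of 15 genes of the ethylene response factor (ERF) family 8 rose and 0 fell (camera adjusted p = 0.00417, and adjusted p = 0.0989 with an estimated correlation). MpERF8 changed by 1.28 ± 0.14 (adjusted p = 2.8e-08) and MpERF18 by 1.47 ± 0.16 (adjusted p = 3.97e-08). Of 13 bZIP genes on the list of nutrient signalling regulators 4 rose and 1 fell over all genes, and 5 rose and 1 fell adjusted over the list alone. Camera gave adjusted p = 0.187 for them. Among 21 nitrate and peptide transporter (NPF) genes 3 rose and 6 fell, with MpNPF31 at -1.18 ± 0.15 (adjusted p = 4.06e-07), and camera gave adjusted p = 0.169. The ammonium transporters moved in different directions: MpAMT2.3 fell by 2.04 ± 0.29 (adjusted p = 2.63e-06), while MpAMT1.4 rose by 0.89 ± 0.17 (adjusted p = 0.000144) and MpAMT1.2 by 0.71 ± 0.15 (adjusted p = 0.000627). Of 6 genes of the MCM replicative helicase 3 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.0653). Of 21 genes on the cell wall word list 5 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.102), and of 21 autophagy genes 1 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.6).

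In all, 4261 of 13504 tested genes were called, 2224 higher and 2037 lower, and 548 of them changed at least 2-fold. Peroxidases, polyphenol oxidases and cupins belong to multigene families whose near-identical members can share reads, so the values of single members are uncertain where the counting split such reads.

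Phosphate starvation raised the transporter genes MpPTB4 and MpPTB8 and lowered MpLPR7. MpPTB4 (Mp4g16560), a phosphate transporter of type B, had 1 count in all 3 control libraries together and 963 counts in the starved ones (12.3 ± 8.33 CPM), a ratio of 933 with a 95% counting interval of 167 to 36900. Its relative MpPTB8 (Mp4g19700) rose by 3.14 ± 0.28, from 21.8 ± 2.96 to 191 ± 86.1 CPM (adjusted p = 3.61e-09). The polyphenol oxidase MpPPO32 (Mp3g24050) rose by 3.62 ± 0.34 (adjusted p = 6.78e-09) and MpERF18 (Mp5g12480) by 1.9 ± 0.16 (adjusted p = 1.01e-09). MpLPR7 (Mp8g04700), of the LOW PHOSPHATE ROOT family of multicopper oxidases, fell by 1.93 ± 0.19, from 69.4 ± 6.43 to 18.2 ± 1.83 CPM (adjusted p = 2.08e-08). The peroxidase MpPOD3 (Mp1g09290) fell by 1.29 ± 0.23 (adjusted p = 0.000133).

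Of 15 genes of phosphate and membrane lipid remodelling 4 rose and 1 fell (camera adjusted p = 0.161): the SPX domain gene MpSPX rose by 0.78 ± 0.08 (adjusted p = 6.04e-08) and the glycerophosphodiester phosphodiesterase MpGDPD by 1.19 ± 0.26 (adjusted p = 0.0012). Of the WRKY genes 9 rose and 0 fell (camera adjusted p = 0.000289, and adjusted p = 0.294 with an estimated correlation). Of the autophagy genes 5 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0257, and adjusted p = 0.829 with an estimated correlation). Fatty acid desaturases were lower, with 5 of 14 fallen and 0 risen (camera adjusted p = 0.0073, and adjusted p = 0.511 with an estimated correlation). Of 28 antioxidant enzymes 2 rose and 11 fell (camera adjusted p = 0.0073, and adjusted p = 0.294 with an estimated correlation). Of 16 genes of isoprenoid precursor synthesis 5 fell and 0 rose (camera adjusted p = 0.0415, and adjusted p = 0.642 with an estimated correlation). Among the 15 ERF genes 6 rose and 0 fell (camera adjusted p = 0.0585). On the word lists, 4 bZIP genes rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.163). On the cell wall list 1 gene rose and 3 fell, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.459). Among the 6 MCM genes the smallest adjusted p over all genes was 0.145, for MpMCM2 (-0.18 ± 0.09), and the list had camera adjusted p = 0.39. In all 3323 genes were called, 1656 higher and 1667 lower, with 384 at least 2-fold; without control replicate 2 the number was 2137. Starved replicate 2 lay apart from its group, at -9.77 and 20.98 on the first 2 principal components against -33.68 and -9.44 for replicate 1 and -36.34 and -11.05 for replicate 3. Without it 3556 genes were called. Of the lists, 7 WRKY genes then rose and 7 desaturases and 6 isoprenoid genes fell, the camera calls above remained (highest adjusted p = 0.0259, and 0.499 to 0.924 with an estimated correlation), and 3 of 7 storage lipid droplet genes rose (camera adjusted p = 0.0259, and 0.304 with an estimated correlation, against 0.0603 and 0.294 with all libraries).

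Sucrose starvation raised MpERF21 from near absence and lowered MpFRO2 and MpNPF31. MpERF21 (Mp5g22160) rose from 0.105 ± 0.0684 to 29.4 ± 17.7 CPM (8.15 ± 1.07, adjusted p = 6.09e-07). The peroxidase MpPOD49 (Mp4g16740) rose by 3.31 ± 0.57 (adjusted p = 3.85e-05), MpWRKY14 by 3.3 ± 0.47 (adjusted p = 2.42e-06) and MpLEA-like59 (Mp8g07630), of the late embryogenesis abundant family, by 3.28 ± 0.33 (adjusted p = 5.78e-09). MpCupin83 fell by 3.09 ± 0.57 (adjusted p = 9.21e-05) and MpFRO2 fell by 2.42 ± 0.19, to 3.8 ± 0.494 CPM (adjusted p = 1.23e-10). The cytochrome P450 MpCYP823A1 (Mp1g19500) fell by 1.83 ± 0.13 (adjusted p = 1.39e-11) and MpNPF31 (Mp7g01820) fell by 1.69 ± 0.16 (adjusted p = 1.92e-09).

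Cell division genes were lower without sucrose. Of 26 genes of cell cycle and replication 1 rose and 14 fell (camera adjusted p = 0.000746, and adjusted p = 0.198 with an estimated correlation). The D-type cyclin MpCYCD_1 fell by 1.14 ± 0.11 (adjusted p = 1.41e-09) and the mitotic kinase MpCDKB fell by 0.94 ± 0.09 (adjusted p = 2.19e-09). Of the 6 MCM genes 5 fell, also adjusted over the list alone (camera adjusted p = 0.00251, and adjusted p = 0.198 with an estimated correlation). Of 12 histone genes 9 fell and 0 rose (camera adjusted p = 0.00144, and adjusted p = 0.198 with an estimated correlation). MpMCM2 fell by 0.65 ± 0.09 (adjusted p = 1.54e-06). Of the 21 genes on the cell wall word list 8 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.0073, and adjusted p = 0.35 with an estimated correlation). MpExpansin6 fell by 1.13 ± 0.15 (adjusted p = 9.8e-07). Of 31 UDP-glycosyltransferases 3 rose and 15 fell (camera adjusted p = 0.00157, and adjusted p = 0.0372 with an estimated correlation). Of the 21 NPF transporters 1 rose and 11 fell (camera adjusted p = 0.019, and adjusted p = 0.0863 with an estimated correlation).

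Of the bZIP, WRKY and ERF genes more rose than fell under sucrose starvation. Of the 13 bZIP genes 6 rose and 1 fell, and 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0101, and adjusted p = 0.198 with an estimated correlation). MpBZIP4 rose by 1.17 ± 0.1 (adjusted p = 1.82e-10) and MpBZIP5 by 0.9 ± 0.08 (adjusted p = 1.38e-09). Of the WRKY genes 9 rose and 1 fell (camera adjusted p = 0.000394, and adjusted p = 0.173 with an estimated correlation) and of the ERF genes 9 rose and 2 fell (camera adjusted p = 0.0119, and adjusted p = 0.149 with an estimated correlation). MpWRKY12 changed by 1.19 ± 0.12 (adjusted p = 3.16e-09) and MpERF8 by 1.42 ± 0.14 (adjusted p = 3.48e-09). Autophagy genes rose in 6 of 21 cases and fell in 0, also adjusted over the list alone (camera adjusted p = 0.139). Of the phosphate and lipid list 6 rose and 1 fell (camera adjusted p = 0.117). In all 4762 genes were called, 2441 higher and 2321 lower, with 735 at least 2-fold. Over the 126 list tests of the 3 starvations camera called 17 and the estimated correlation kept 1, the UDP-glycosyltransferases under sucrose starvation.

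The responses to the 3 starvations overlapped. Nitrate and phosphate starvation raised 1140 genes in common and lowered 1168, against 273 and 251 for independent lists, and 14 genes moved in opposite directions against 524. Nitrate and sucrose starvation shared 1269 raised and 890 lowered genes (independent 402 and 350), and phosphate and sucrose starvation shared 914 and 670 (independent 299 and 287). These pairs had 163 and 111 in opposite directions (independent 750 and 586). Phosphate and sucrose shared a total of 1584, and 943 without control replicate 2. All 3 starvations raised 740 genes and lowered 505 (independent 49 and 43). MpERF8, MpWRKY10, MpCupin83 and MpExpansin32 were each called in the same direction in all 3. Across genes the fold changes had covariances of 0.204, 0.226 and 0.175, and unchanged groups simulated against the same controls gave 0.0248. Correlations were 0.588, 0.6 and 0.459 (simulated 0.508). The control libraries were not split and their harvest day is not given, so shared controls or age may add to the excess.

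**Figure D1:**
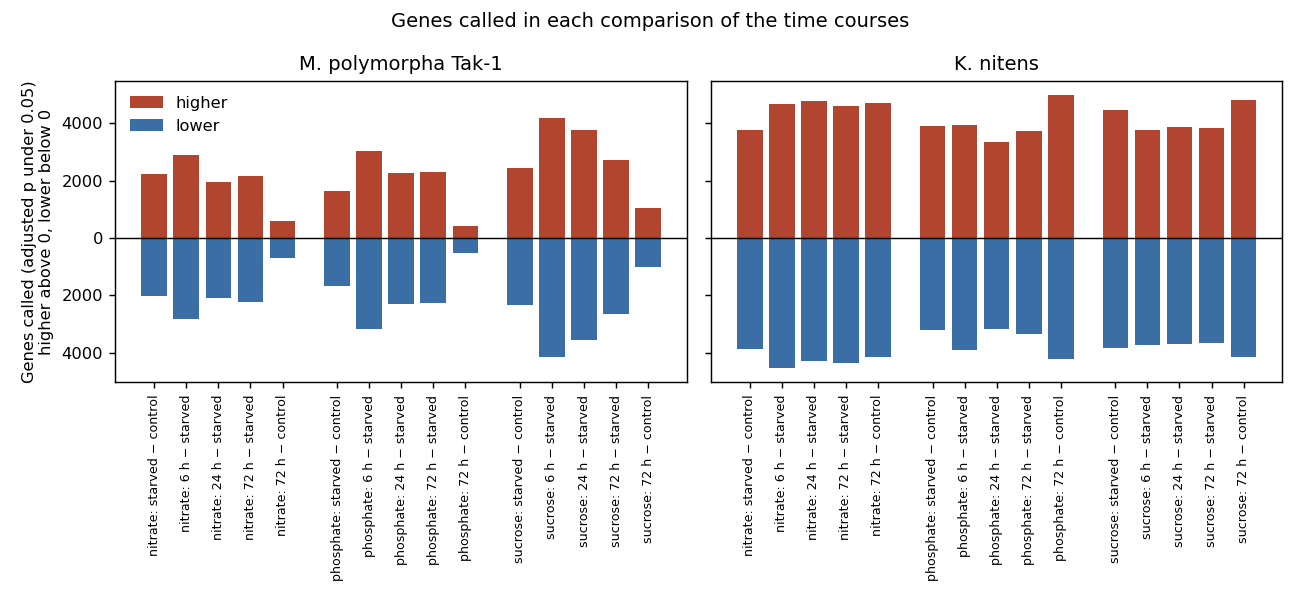
Bars give the number of genes called higher (above 0) and lower (below 0) in each comparison of the M. polymorpha and K. nitens time courses, edgeR adjusted p under 0.05, 3 libraries per group. At 72 h against control the M. polymorpha bars are the shortest of their panel (1307, 958 and 2054 genes in all), and those of K. nitens hold 8854, 9202 and 8964 genes.

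After 6 h of nitrate resupply MpExpansin32 and the transporter MpNPF33 were higher than in starved plants, and MpPPO2 was lower. MpExpansin32 rose by 1.92 ± 0.17 against the starved group, to 103 ± 32.3 CPM (adjusted p = 5.12e-10), and MpNPF33 rose by 2.73 ± 0.31, from 3.81 ± 0.674 to 25.3 ± 2.38 CPM (adjusted p = 3.75e-08). MpPPO2 fell by 4.68 ± 0.46 (adjusted p = 2.65e-09), and MpMLS5 fell by 3.99 ± 0.51, from 281 ± 15 to 17.8 ± 10.4 CPM (adjusted p = 2.54e-07). All 6 MCM genes were higher (camera adjusted p = 0.00207, and adjusted p = 0.227 with an estimated correlation). Of the histones 10 rose and 1 fell and of the cell cycle genes 13 rose and 3 fell (both camera adjusted p = 0.00145, and both adjusted p = 0.227 with an estimated correlation). Of the NPF transporters 10 rose and 1 fell (camera adjusted p = 0.00867, and adjusted p = 0.0646 with an estimated correlation). The bZIP genes fell in 8 cases and rose in 0, or fell in 10 adjusted over the list alone (camera adjusted p = 0.00145, and adjusted p = 0.205 with an estimated correlation). Of the ERF genes 1 rose and 9 fell (camera adjusted p = 0.0299, and adjusted p = 0.205 with an estimated correlation).

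At 24 h MpExpansin32 was 2.16 ± 0.17 above the starved level (adjusted p = 3.5e-10) and MpLPR7 had risen by 1.42 ± 0.19, to 92.2 ± 3.87 CPM (adjusted p = 1.23e-06). At 72 h MpCupin83 was 2.56 ± 0.55 above the starved level (adjusted p = 0.000553). All 10 called WRKY genes were lower (camera adjusted p = 0.000178, and adjusted p = 0.183 with an estimated correlation). MpWRKY10 fell by 1.26 ± 0.12 (adjusted p = 6.09e-09). Against the starved group, 5709 genes were called at 6 h (2885 higher, 2824 lower), 4036 at 24 h (1941 and 2095) and 4387 at 72 h (2154 and 2233).

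Resupply of phosphate lowered the phosphate transporters and raised MpLPR7. MpPTB4 changed by -4 ± 0.65 at 6 h (adjusted p = 9e-06), and its level was 0.761 ± 0.418 CPM against 12.3 ± 8.33 CPM in the starved group and 0.0829 CPM at 72 h. MpPTB8 was 3.19 ± 0.29 lower at 72 h on the log2 scale (-3.19, adjusted p = 2.85e-09), at 20.8 ± 4.28 CPM against 191 ± 86.1. MpPOD161 rose by 5.35 ± 0.35 at 6 h (adjusted p = 9.74e-13), from 1.07 ± 0.129 to 44.2 ± 13.8 CPM. MpCYP707A, of the family that breaks down abscisic acid, rose by 2.82 ± 0.43 (adjusted p = 3.22e-06). MpMLS5 fell by 5.05 ± 0.55 (adjusted p = 1.74e-08). MpLPR7 rose by 2.32 ± 0.2 at 24 h, to 91.1 ± 20 CPM (adjusted p = 6.21e-10). Of the 21 autophagy genes 20 fell and 0 rose at 6 h, also adjusted over the list alone (camera adjusted p = 2.86e-08, and adjusted p = 0.463 with an estimated correlation). MpATG18b changed by -0.51 ± 0.06 (adjusted p = 7.21e-08). Of the antioxidant enzymes 13 rose and 2 fell at 6 h (camera adjusted p = 0.012, and adjusted p = 0.463 with an estimated correlation). Of the isoprenoid genes 9 rose and 0 fell (camera adjusted p = 0.0211, and adjusted p = 0.597 with an estimated correlation). Called genes against the starved group numbered 6211 at 6 h (3023 higher, 3188 lower), 4579 at 24 h (2276 and 2303) and 4563 at 72 h (2286 and 2277).

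Resupply of sucrose called more genes than that of nitrate or phosphate at each time. At 6 h the glutathione S-transferase MpGST9 rose by 3.3 ± 0.19, from 62.6 ± 8.57 to 616 ± 42.5 CPM (adjusted p = 4.7e-15). MpPKS/CHS10, named for flavonoid synthesis, rose by 3.25 ± 0.22 (adjusted p = 9.02e-14). MpERF21 fell by 6.33 ± 0.93 (adjusted p = 5.44e-07), MpGDPD fell by 4.03 ± 0.3, from 272 ± 46.8 to 16.6 ± 6.84 CPM (adjusted p = 9.04e-13), and MpBZIP4 fell by 2.06 ± 0.1 (adjusted p = 2.65e-16). The 5 HSP90 chaperone genes rose, also adjusted over the list alone (camera adjusted p = 0.00645, and adjusted p = 0.475 with an estimated correlation). Of the 21 autophagy genes 1 rose and 18 fell, or 1 and 19 adjusted over the list alone (camera adjusted p = 0.000102, and adjusted p = 0.487 with an estimated correlation). Of the cell cycle genes 16 rose and 4 fell (camera adjusted p = 0.0324, and adjusted p = 0.508 with an estimated correlation). Of 13 shikimate pathway genes 9 rose and 2 fell (camera adjusted p = 0.0324, and adjusted p = 0.487 with an estimated correlation).

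At 24 h of sucrose resupply MpGH16.31, 2 peroxidases and MpPPO14 were counted that had at most 3 counts in the starved group. MpGH16.31 (Mp4g01200) had 0 counts in the starved libraries and 1595 after resupply (19.5 ± 4.41 CPM), at least 422-fold higher with 3 counts allowed over the starved group. The peroxidases MpPOD154 and MpPOD29 had ratios of 890 (95% counting interval 246 to 7360; 2243 counts against 2) and 737 (252 to 3580; 2786 against 3), and MpPPO14 had 1170 (210 to 46400; 1478 against 1). Of 70 peroxidases 40 rose and 10 fell (camera adjusted p = 0.0033, and adjusted p = 0.562 with an estimated correlation). Of the cell wall list 16 rose and 0 fell, or 17 adjusted over the list alone (camera adjusted p = 1.5e-05, and adjusted p = 0.284 with an estimated correlation). At 72 h MpNPF31 had risen by 1.8 ± 0.16, to 11.6 ± 1.05 CPM (adjusted p = 4.69e-10). MpWRKY14 was lower (-3.61 ± 0.49, adjusted p = 9.5e-07). At that time 12 NPF transporters rose and 0 fell (camera adjusted p = 0.000768, and adjusted p = 0.0037 with an estimated correlation), as did 16 UDP-glycosyltransferases against 1 that fell (camera adjusted p = 0.00156, and adjusted p = 0.0275 with an estimated correlation). Called genes numbered 8308 at 6 h (4170 higher, 4138 lower), 7347 at 24 h (3781 and 3566) and 5341 at 72 h (2707 and 2634). Over the 378 list tests of resupply camera called 84, and the estimated correlation kept 2, the NPF transporters and the UDP-glycosyltransferases at 72 h of sucrose.

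**Figure D2:**
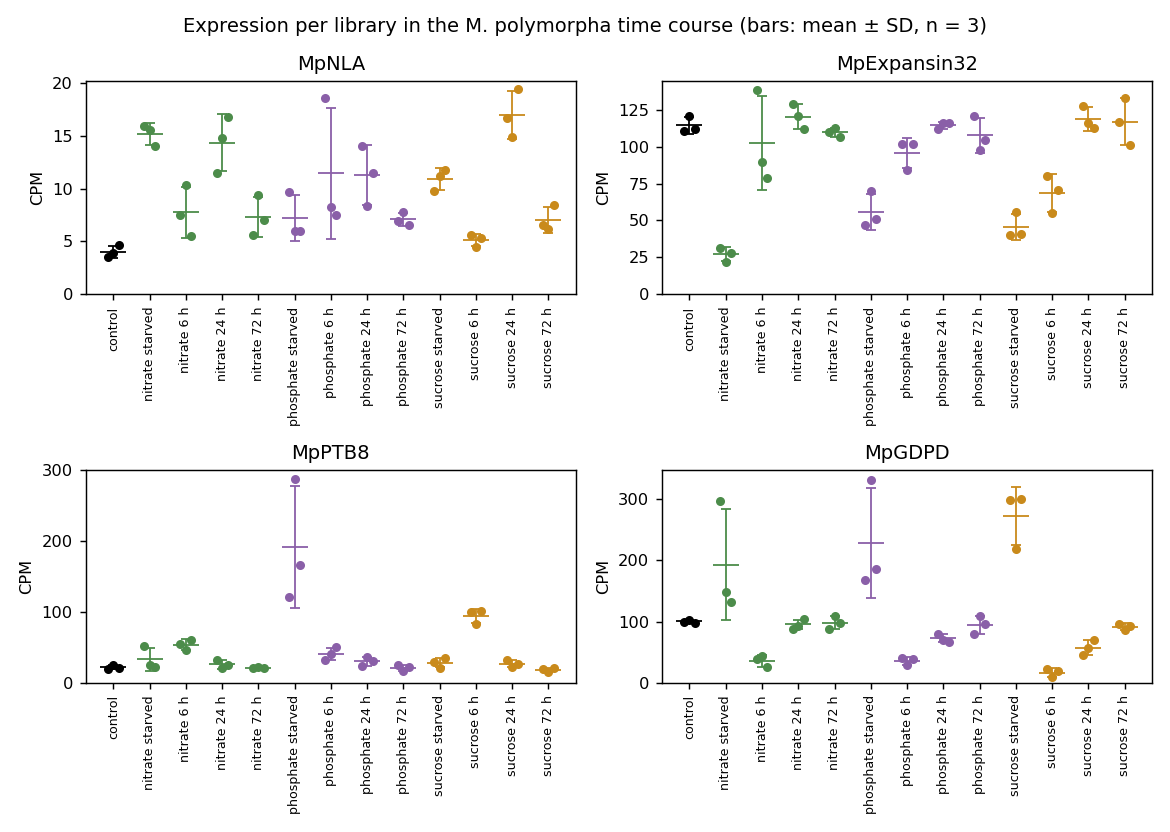
Points show CPM of MpNLA, MpExpansin32, MpPTB8 and MpGDPD in each wild-type library of the time course, by nutrient and stage, with means of 3 libraries. MpPTB8 reaches 191 CPM after phosphate starvation and 20.8 CPM at 72 h of resupply.

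After 72 h of resupply MpLTP-like65 and MpARFD2 were still above control after each nutrient. The lipid transfer protein gene MpLTP-like65 was higher after each nutrient (1.36 ± 0.31, adjusted p = 0.00547 after nitrate; 1.5 ± 0.31, adjusted p = 0.00371 after phosphate; 1.38 ± 0.31, adjusted p = 0.00273 after sucrose). The auxin response factor MpARFD2 was also higher after each, at 28.8, 27.5 and 30 CPM against 16 ± 2.63. MpNLA was still higher after nitrate resupply, at 7.34 ± 1.9 CPM (0.88 ± 0.28, adjusted p = 0.0422), and MpFRO2 lower (-0.65 ± 0.17, adjusted p = 0.0161). After sucrose resupply MpFRO2 (-0.8 ± 0.17, adjusted p = 0.00237) and MpMCM2 (-0.4 ± 0.09, adjusted p = 0.00249) were lower. Of 73 receptor-like kinases 8, 6 and 10 were lower and 0 were higher after nitrate, phosphate and sucrose (camera adjusted p = 0.000649, 0.000493 and 0.0169, and adjusted p = 0.0467, 0.0543 and 0.178 with an estimated correlation). Of 5 genes known from oil body cells 2, 0 and 2 were lower in the same comparisons (camera adjusted p = 0.0161, 0.215 and 0.0571, and adjusted p = 0.181, 0.605 and 0.308 with an estimated correlation). Leaving out 1 library ended some of these calls. After nitrate, those of MpLTP-like65 and MpARFD2 ended without control replicate 1, that of MpFRO2 without replicate 1 or 2 of either group, and that of MpNLA without any library but resupplied replicate 1 (highest adjusted p = 0.0505, 0.0563, 0.0833 and 0.226). After phosphate that of MpARFD2 ended without control replicate 1 or 3 or resupplied replicate 3 (0.0958). Genes that differed from control numbered 1307 after nitrate (600 higher, 707 lower), 958 after phosphate (419 and 539) and 2054 after sucrose (1051 and 1003). Leaving out 1 library gave 509 (without control replicate 1) to 851, 342 (without phosphate 72 h replicate 3) to 702, and 1147 (without sucrose 72 h replicate 2) to 1857. Of the genes called after starvation, 509 of 4261 (11.9%), 160 of 3323 (4.81%) and 722 of 4762 (15.2%) were still called in the same direction at 72 h, against 205, 118 and 362 for independent lists, and 67, 79 and 118 in the opposite direction against 207, 118 and 362. Shared controls or age may add to the excess.

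In K. nitens, starvation of phosphate raised gene-KFL_001640120 from 17.1 ± 3.03 to 1170 ± 588 CPM (6.11 ± 0.36, adjusted p = 2.99e-14) and gene-KFL_002720150 from 5.5 ± 0.547 to 192 ± 72.8 CPM (5.12 ± 0.28, adjusted p = 1.06e-14). It lowered gene-KFL_002950010 from 16.6 ± 4.26 to 1.67 ± 0.396 CPM (-3.31 ± 0.4, adjusted p = 4.68e-08) and gene-KFL_009900010 from 164 ± 38.5 to 17.9 ± 3.22 CPM (-3.19 ± 0.24, adjusted p = 5.99e-12). No names accompany these identifiers. Nitrate starvation changed 7662 of 12176 tested genes (3780 higher, 3882 lower; 1520 at least 2-fold), phosphate starvation 7107 (3894 and 3213; 1254) and sucrose starvation 8287 (4450 and 3837; 2216). Nitrate and sucrose starvation shared 2759 raised and 2484 lowered genes, against 1381 and 1223 for independent lists, and 535 genes moved in opposite directions against 2610. Nitrate and phosphate starvation shared 1763 and 1464 (independent 1209 and 1024) with 1487 in opposite directions (independent 2239), and phosphate and sucrose starvation shared 2467 and 1878 (independent 1423 and 1013) with 936 in opposite directions (independent 2401). The covariances of fold changes were 0.446, 0.118 and 0.241 in that order, against a simulated 0.0173. The correlations were 0.668, 0.222 and 0.383 against a simulated 0.511. Shared controls or age may add to the excess.

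Resupplied K. nitens differed from control at every time. Against the starved group 9239, 9081 and 8956 genes were called at 6, 24 and 72 h of nitrate, 7863, 6528 and 7087 of phosphate, and 7488, 7575 and 7467 of sucrose. At 72 h against control 8854 genes were called after nitrate (4707 higher, 4147 lower), 9202 after phosphate (4999 and 4203) and 8964 after sucrose (4823 and 4141). Of the starvation calls 53.2% for nitrate, 85.4% for phosphate and 69% for sucrose were still called in the same direction at 72 h, against 36.3%, 38.1% and 37% for independent lists, and 1743, 195 and 919 genes in the opposite direction against 2788, 2663 and 3033. Shared controls or age may add to the excess. All 3 nutrients shared 4186 raised and 3517 lowered genes at 72 h (independent 765 and 487), and the fold changes of the pairs had covariances of 0.926 to 1.03 against a simulated 0.017. On the first principal component the 27 resupply libraries lay between 13.14 and 34.77 and the 12 control and starved libraries between -87.18 and -23.84. Whether the resupply libraries were prepared apart from the others is not in the labels, and such a batch and the resupply cannot be told apart. The species were not compared gene by gene, because no map between their genes was used here.

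The mutated genes were still counted in their own mutants, and a count over a whole gene does not show a small edit. Under control conditions MpCSD (Mp1g04040) had 683 ± 13.1 CPM in Mpcsd-2 and 814 ± 36.7 in Tak-1 (-0.25 ± 0.06, adjusted p = 0.000876), and it was lower also in Mperf20-21 (-0.42 ± 0.06, adjusted p = 1.03e-05) and Mphd9-14 (-0.43 ± 0.06, adjusted p = 6.55e-06). MpERF20 (Mp5g06970), also listed as MpLAXR, had 6.59 ± 0.482 CPM in Mperf20-21 and 11.8 ± 1.29 in Tak-1 (-0.84 ± 0.13, adjusted p = 3.81e-05), and it was lower in Mphd9-14 (-0.71 ± 0.13, adjusted p = 0.000215). MpHD9 (Mp1g01010) had 34.3 ± 1.22 CPM in Mphd9-14 and 46.6 ± 2.43 in Tak-1 (-0.44 ± 0.07, adjusted p = 5.99e-05), and it was lower in Mpcsd-2 (-0.33 ± 0.07, adjusted p = 0.000649) and Mperf20-21 (-0.23 ± 0.07, adjusted p = 0.0141, at most 0.0759 with replicate 2 of either genotype left out). In the mutant starvation set MpCSD was higher in the libraries labelled Mpcsd-2 than in the other mutants, which goes against a loss of its transcript. Control levels were 664 ± 70.5 CPM against 459 ± 35.7 in Mperf20-21 (0.53 ± 0.09, adjusted p = 6.74e-05) and 474 ± 19.5 in Mphd9-14 (0.49 ± 0.09, adjusted p = 0.000206). Without nitrate, phosphate and sucrose they were 612 ± 74, 584 ± 67.5 and 592 ± 34 CPM in Mpcsd-2, means of 447, 426 and 405 in Mperf20-21 and 478, 454 and 416 in Mphd9-14. Control levels were 3.08 CPM for MpERF20 in Mperf20-21, 4.63 in Mpcsd-2 and 2.36 in Mphd9-14, and 22.1 CPM for MpHD9 in Mphd9-14, 30.1 in Mpcsd-2 and 25.1 in Mperf20-21. In starved plants MpERF20 had 2.46 ± 0.0647, 2.42 ± 0.893 and 1.87 ± 0.648 CPM (the last with n = 2) in Mperf20-21, and MpHD9 20.9 ± 1.85, 22.8 ± 0.575 and 20.5 ± 1.94 CPM in Mphd9-14. These levels do not tell the mutants from wild type by themselves, so the genotypes rest on the labels.

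**Figure D3:**
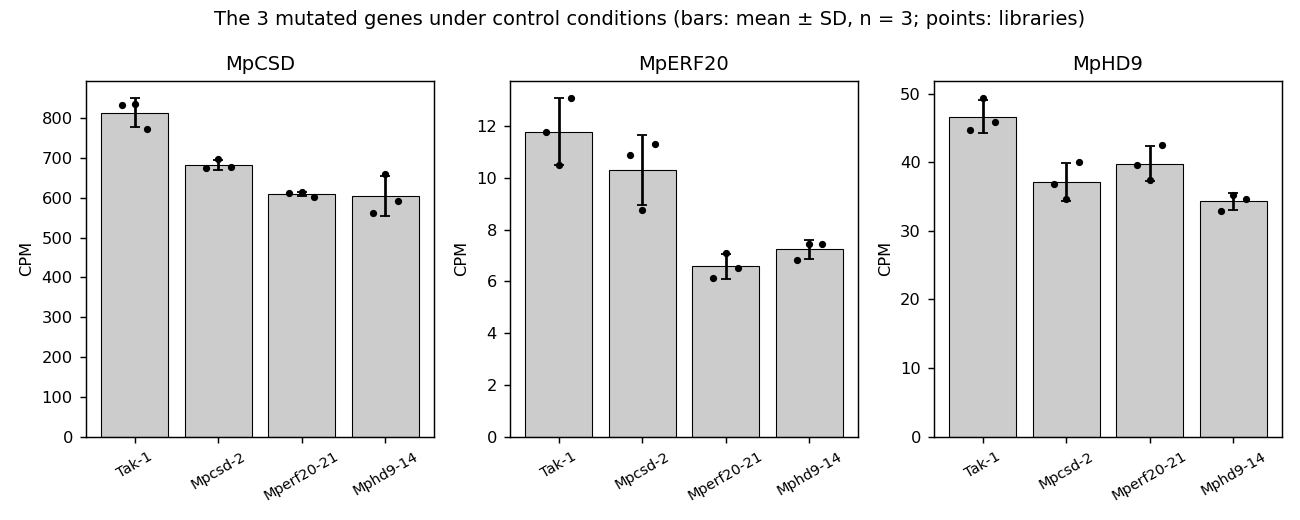
Points show CPM of MpCSD, MpERF20 and MpHD9 in each library of the control-condition set, for Tak-1 and each mutant. Bars give the mean ± SD of each genotype. MpERF20 lies at 6.59 CPM in Mperf20-21 and at 11.8 CPM in Tak-1 under control conditions.

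In wild type all 3 genes rose at 6 h of resupply, and MpCSD and MpHD9 fell under some starvations. MpCSD fell by 0.24 ± 0.07 without phosphate (adjusted p = 0.0181) and fell by 0.28 ± 0.07 without sucrose (adjusted p = 0.00341), and was -0.1 ± 0.07 without nitrate (adjusted p = 0.322). At 6 h of resupply it rose by 0.24 ± 0.07, 0.46 ± 0.07 and 0.86 ± 0.07 for nitrate, phosphate and sucrose (adjusted p = 0.0103, 7.51e-06 and 1.86e-11), reaching 801 ± 79 CPM with sucrose. MpERF20 was not called after any starvation (adjusted p = 0.813, 0.981 and 0.69) and rose at 6 h by 1.32 ± 0.28, 1.36 ± 0.28 and 1.5 ± 0.29 (adjusted p = 0.000276, 0.000159 and 3.51e-05). MpHD9 fell by 0.24 ± 0.08 without nitrate and fell by 0.3 ± 0.08 without sucrose (adjusted p = 0.024 and 0.00548), was -0.16 ± 0.08 without phosphate (adjusted p = 0.151), and rose at 6 h by 0.56 ± 0.08, 0.5 ± 0.08 and 0.8 ± 0.08 (adjusted p = 1.99e-06, 9.43e-06 and 6.47e-10). The nitrate call of MpHD9 ended without control or starved replicate 3 (highest adjusted p = 0.14). The call of MpCSD ended without control replicate 2 or 3 or starved replicate 3 for phosphate starvation, and without starved replicate 3 for nitrate resupply (highest adjusted p = 0.131 and 0.0585). At 72 h against control the smallest adjusted p over the 3 genes and nutrients was 0.244, for MpERF20 after nitrate (0.54 ± 0.28).

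Under control conditions MpGH31.1 was higher in all 3 mutants, MpHA11 and MpPOD41 in Mpcsd-2, and MpUGT11 in Mperf20-21 and Mphd9-14. In Mpcsd-2 the proton pump MpHA11 rose by 4.4 ± 0.2, from 4.55 ± 1.46 to 95.8 ± 21.7 CPM (adjusted p = 2.56e-12). The peroxidases MpPOD41 and MpPOD25 rose by 5.05 ± 0.41 (adjusted p = 8.17e-09) and 3.81 ± 0.12 (adjusted p = 3.95e-14). MpSQC2 fell by 4.18 ± 0.31 (adjusted p = 2.5e-09). In Mperf20-21 and Mphd9-14 the UDP-glycosyltransferase MpUGT11 rose by 4.41 ± 0.25 (adjusted p = 1.63e-10) and 4.18 ± 0.25 (adjusted p = 2.72e-10). The ammonium transporter MpAMT2.3 rose there by 2.55 ± 0.25 (adjusted p = 2.16e-07) and 2.25 ± 0.26 (adjusted p = 1.21e-06). MpGH31.1 rose in all 3 (4.12 ± 0.25, 4.21 ± 0.25 and 4.69 ± 0.25; adjusted p = 1.57e-10, 3.19e-10 and 5.32e-11).

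Autophagy genes were higher in all 3 mutants. In Mpcsd-2, Mperf20-21 and Mphd9-14, 13, 14 and 15 of 21 rose and 1, 0 and 1 fell. Adjusted over the list alone, 13, 14 and 15 rose and 2, 0 and 1 fell (camera adjusted p = 0.0357, 0.00451 and 0.000707, and adjusted p = 0.497, 0.459 and 0.486 with an estimated correlation). MpATG8b rose by 0.69 ± 0.05 (adjusted p = 5.2e-09), 0.42 ± 0.05 (adjusted p = 6.9e-06) and 0.46 ± 0.05 (adjusted p = 2.09e-06). In Mpcsd-2 all 5 genes known from oil body cells were lower (camera adjusted p = 0.0104, and adjusted p = 0.229 with an estimated correlation), in Mperf20-21 0 and in Mphd9-14 2 (camera adjusted p = 0.704 and 0.177). MpC1HDZ fell by 1.63 ± 0.09 (adjusted p = 2.61e-11) and MpABCG1 fell by 2.16 ± 0.14 (adjusted p = 5.05e-10). Of 5 aquaporins 5, 2 and 3 were lower and 0, 1 and 1 higher (camera adjusted p = 0.0141, 0.546 and 0.319, and for the first adjusted p = 0.229 with an estimated correlation). In Mperf20-21 and Mphd9-14, 11 and 9 of 18 cell wall genes rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.00451 and 0.00155, and adjusted p = 0.386 and 0.486 with an estimated correlation). In Mpcsd-2, 4 rose and 5 fell, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.773). Of 6 MCM genes 6, 3 and 6 were lower in Mpcsd-2, Mperf20-21 and Mphd9-14, or 6, 5 and 6 adjusted over the list alone (camera adjusted p = 0.0844, 0.133 and 0.0174, and for the last adjusted p = 0.539 with an estimated correlation). Of 12565 tested genes 7135 differed in Mpcsd-2 (3550 higher, 3585 lower), 5192 in Mperf20-21 (2634 and 2558) and 5491 in Mphd9-14 (2723 and 2768).

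The differences of Mperf20-21 and Mphd9-14 from Tak-1 shared 2057 raised and 2023 lowered genes (independent 571 and 564) and 23 in opposite directions (independent 1135). Mpcsd-2 shared 1737 and 1490 with Mperf20-21 (independent 744 and 730) and 1966 and 1778 with Mphd9-14 (independent 769 and 790), with 461 and 310 in opposite directions (independent 1474 and 1559). Covariances were 0.292, 0.253 and 0.32 against a simulated 0.018, and correlations 0.823, 0.511 and 0.596 against a simulated 0.502; part of the excess may come from the shared controls. Against the Tak-1 control of the time course, a comparison across experiments, the mutant controls of the starvation set gave differences that correlated with these at 0.157, 0.052 and 0.137 across genes, which are not independent replicates.

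Nitrate starvation raised MpPOD89 and MpPPO4 in all 3 mutants relative to their own controls. In Mpcsd-2 MpPPO4 rose by 2.41 ± 0.21, from 3.97 ± 0.75 to 21.2 ± 1.64 CPM (adjusted p = 3.85e-08), and MpPOD89 by 2.34 ± 0.42 (adjusted p = 0.00126). In Mperf20-21 MpPOD89 rose by 3.24 ± 0.37, from 9 ± 0.762 to 84.9 ± 16.5 CPM (adjusted p = 8.1e-06). MpPPO4 rose by 1.42 ± 0.17 (adjusted p = 1.36e-05). In Mphd9-14 MpPOD89 rose by 2.14 ± 0.4 (adjusted p = 0.00428) and MpPPO4 by 0.75 ± 0.18 (adjusted p = 0.0314). MpLTP-like68 was lower in all 3 mutants (-0.63 ± 0.12, -0.79 ± 0.12 and -0.76 ± 0.12; adjusted p = 0.00223, 0.000167 and 0.00113). Of 13 pathogenesis-related genes 8 rose in Mpcsd-2 (camera adjusted p = 4.26e-11, and adjusted p = 0.000278 with an estimated correlation) and 7 in Mperf20-21 (camera adjusted p = 4.8e-11, and adjusted p = 0.000247 with an estimated correlation). MpPR5b rose by 1.52 ± 0.21 and 1.09 ± 0.17 (adjusted p = 4.28e-05 and 0.000175). In Mphd9-14, 7 of 27 polyphenol oxidases rose (camera adjusted p = 7.85e-08, and adjusted p = 0.0464 with an estimated correlation). In Mpcsd-2 the cell wall word list and the expansins had medians of -0.224 and -0.151, means of 0.124 and 0.111, and tests toward lower (camera adjusted p = 0.0128 and 0.0298, and adjusted p = 0.126 and 0.161 with an estimated correlation). Called genes numbered 243 in Mpcsd-2 (221 higher, 22 lower), 428 in Mperf20-21 (322 and 106) and 160 in Mphd9-14 (141 and 19). With 1 library left out they were 98 (without starved replicate 1) to 467 (without starved replicate 3), 164 (without starved replicate 1) to 425, and 45 (without control replicate 2) to 110. When only the compared groups were fitted, 30 genes were called in Mpcsd-2 and 572 in Mphd9-14. The calls of MpPR5b and MpLTP-like68 in Mpcsd-2 ended in that fit (adjusted p = 0.15 and 0.0561). In Mphd9-14 the call of MpPOD89 ended without starved replicate 1 and that of MpPPO4 without that library or any control replicate (highest adjusted p = 0.0576 and 0.295).

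Phosphate starvation raised MpPTB4, MpPTB8 and MpPPO32 and lowered MpLPR7 in all 3 mutants. MpPTB8 rose by 3.68 ± 0.16, 2.81 ± 0.16 and 2.8 ± 0.16 in Mpcsd-2, Mperf20-21 and Mphd9-14 (adjusted p = 2.15e-16, 6.8e-14 and 1.45e-13), to 283 ± 32.6, 206 ± 36.3 and 217 ± 16 CPM. MpPTB4 had 5178 counts against 2 in Mpcsd-2 (ratio 2430, 95% counting interval 671 to 20000), 1315 against 2 in Mperf20-21 (875, interval 242 to 7230) and 1049 against 0 in Mphd9-14 (at least 396-fold). MpPPO32 rose by 3.59 ± 0.22, 3.86 ± 0.21 and 3.68 ± 0.21 (adjusted p = 2.63e-13, 2.82e-14 and 2.01e-13), and MpLPR7 was lower (-1.48 ± 0.14, -1.45 ± 0.14 and -1.53 ± 0.14; adjusted p = 2.88e-09, 1.35e-08 and 6.48e-09). Of 14 genes of phosphate and membrane lipid remodelling 5 rose in Mpcsd-2 (camera adjusted p = 4.4e-05, and adjusted p = 0.0724 with an estimated correlation). In Mphd9-14, 1 of the 14 rose (camera adjusted p = 0.0454, and adjusted p = 0.283 with an estimated correlation). Peroxidases rose in 28, 23 and 18 of 65 cases and fell in 0 (camera adjusted p = 4.29e-12, 8.78e-15 and 1.68e-19, and adjusted p = 0.0724, 0.085 and 0.0265 with an estimated correlation). Genes on the cell wall word list rose in 8, 6 and 6 cases and fell in 0. Adjusted over the list alone, they rose in 9, 9 and 7 and fell in 1, 2 and 0 (camera adjusted p = 0.00448, 0.0075 and 0.000231, and adjusted p = 0.0756, 0.085 and 0.0265 with an estimated correlation). Called genes numbered 1026 (842 higher, 184 lower), 602 (501 and 101) and 303 (262 and 41). Leaving out 1 library gave 626 (without starved replicate 2) to 1070, 372 (without control replicate 1) to 450 and 163 (without starved replicate 2) to 261, and a fit of the compared groups alone gave 542, 906 (662 and 244) and 707.

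Sucrose starvation lowered MpPL1.3 and genes on the cell wall word list in all 3 mutants. MpPL1.3, named for the pectate lyase family, fell from 227 ± 12.9 to 46.5 ± 8.71 CPM in Mpcsd-2 (-2.28 ± 0.11, adjusted p = 1.21e-14), and it changed by -1.89 ± 0.13 in Mperf20-21 (adjusted p = 9.71e-11) and -2.01 ± 0.11 in Mphd9-14 (adjusted p = 3.74e-13). MpExpansin32 changed by -1.46 ± 0.13, -2.16 ± 0.17 and -1.61 ± 0.14. MpWRKY14 rose by 2.42 ± 0.52, 1.92 ± 0.55 and 4.11 ± 0.6 (adjusted p = 0.00106, 0.016 and 9.91e-06). Of 22 genes on the cell wall word list 10, 9 and 11 fell and 0 rose, or 10, 9 and 12 fell adjusted over the list alone (camera adjusted p = 1.36e-05, 5.37e-05 and 1.07e-05, and adjusted p = 0.0147, 0.0254 and 0.0125 with an estimated correlation). WRKY genes rose in 9, 5 and 7 cases and fell in 0 (camera adjusted p = 0.000571, 0.00111 and 0.000185, and adjusted p = 0.116, 0.121 and 0.0432 with an estimated correlation). Called genes numbered 3442 in Mpcsd-2 (2009 higher, 1433 lower), 2019 in Mperf20-21 with 2 starved libraries (1103 and 916) and 2949 in Mphd9-14 (1634 and 1315). They were 1845 in Mpcsd-2 without starved replicate 2 and 249 with the compared groups alone, 793 in Mperf20-21 without starved replicate 1, and 1800 in Mphd9-14 without starved replicate 2. In Mpcsd-2 the call of MpWRKY14 ended with the compared groups alone (adjusted p = 0.0945), and in Mperf20-21 that of MpWRKY14 ended without control replicate 2 or 3 or either starved replicate (0.123).

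Genes changed by nitrate starvation in Tak-1 changed less in mutants of another experiment. Over 498 genes changed at least 2-fold in Tak-1, the median change in the Tak-1 direction was 1.36 in Tak-1 and 0.25, 0.11 and 0.05 in Mpcsd-2, Mperf20-21 and Mphd9-14. For phosphate (340 genes) the medians were 1.49 against 0.71, 0.63 and 0.35, and for sucrose (690 genes) 1.45 against 0.95, 0.78 and 0.94. Picking genes by size in Tak-1 favours Tak-1, and genotype was not told from experiment. MpExpansin32 under nitrate starvation differed from wild type by 1.75 ± 0.21, 2.03 ± 0.21 and 2.07 ± 0.21 (interaction adjusted p = 1.01e-06, 5.83e-08 and 3.21e-08). Its mutant levels were 94.9 against 118, 67.5 against 69.3 and 101 against 102 CPM, starved against own control. MpERF8 (-0.86 ± 0.17, -1.3 ± 0.17 and -1.36 ± 0.17; adjusted p = 0.000949, 1.38e-06 and 8.55e-07) and MpWRKY9 (-0.7 ± 0.16, -1.24 ± 0.16 and -0.88 ± 0.16; adjusted p = 0.00362, 1.38e-06 and 0.000195), which rose in wild type, also differed. MpNLA was called in Mperf20-21 (-1.87 ± 0.54, adjusted p = 0.0153) and Mphd9-14 (-2.11 ± 0.55, adjusted p = 0.00706) and not in Mpcsd-2 (-1.6 ± 0.57, adjusted p = 0.0678), where it was called without control replicate 2 or starved replicate 1 (lowest adjusted p = 0.0134). The call of MpNLA in Mperf20-21 ended without starved replicate 1 (adjusted p = 0.0543).

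The interaction for phosphate was not called for the transporter MpPTB8 (0.53 ± 0.34, -0.34 ± 0.33 and -0.35 ± 0.33; adjusted p = 0.387, 0.638 and 0.619) nor for MpLPR7 (adjusted p = 0.186, 0.186 and 0.276). It was called for MpPOD3 (1.29 ± 0.28, 1.28 ± 0.28 and 1.22 ± 0.28; adjusted p = 0.00379, 0.00562 and 0.00792). Under sucrose starvation MpBZIP4 rose less in the mutants (-0.87 ± 0.15, -0.8 ± 0.16 and -0.63 ± 0.15; adjusted p = 0.000547, 0.00509 and 0.0119), as did MpWRKY9 (-0.65 ± 0.16, -0.9 ± 0.17 and -0.84 ± 0.16; adjusted p = 0.018, 0.00327 and 0.00147). MpERF21 differed in Mpcsd-2 (-6.72 ± 1.48, adjusted p = 0.00854) and Mperf20-21 (-7.9 ± 1.63, adjusted p = 0.00663), and had adjusted p = 0.196 in Mphd9-14. In Mperf20-21 the calls of MpBZIP4, MpWRKY9 and MpERF21 ended without starved replicate 1 (highest adjusted p = 0.0674, 0.0556 and 0.0947), the last also without control replicate 1 or starved replicate 2. In Mpcsd-2 those of MpWRKY9, MpBZIP4 and MpERF21 ended with the 4 compared groups alone (highest adjusted p = 0.353, 0.0551 and 0.142), the first also without control replicate 2 or starved replicate 1 of Mpcsd-2 or of Tak-1. In Mphd9-14 that of MpBZIP4 ended without its control or starved replicate 3, Tak-1 control replicate 1 or Tak-1 starved replicate 1 (0.0666). DESeq2 and the 4 groups alone called MpERF21 in Mphd9-14 (lowest adjusted p = 0.00307), the latter also MpLPR7 in Mperf20-21 (adjusted p = 0.0468), and without Tak-1 starved replicate 2 MpPTB8 was called in Mpcsd-2 (adjusted p = 0.0357). Of 16 ERF genes 5, 6 and 5 responded lower than in wild type to nitrate starvation and 4, 6 and 5 to sucrose starvation, and 0 higher (camera adjusted p = 0.00562, 0.00372, 0.00758, 0.00249, 4.97e-05 and 0.000479, and adjusted p = 0.0381, 0.0144, 0.0248, 0.018, 0.000491 and 0.00228 with an estimated correlation). Of the WRKY genes 10 in Mperf20-21 responded lower to nitrate starvation (camera adjusted p = 2.55e-05, and adjusted p = 0.0189 with an estimated correlation).

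Interaction calls for nitrate, phosphate and sucrose numbered 1402, 855 and 353 in Mpcsd-2, 1893, 607 and 159 in Mperf20-21 and 1934, 642 and 340 in Mphd9-14. With the 4 compared groups alone they were 984, 547 and 20, 2630, 1005 and 371, and 3211, 1453 and 618. Leaving out 1 library moved several counts by more than 1.5 times. Nitrate in Mpcsd-2 gave 884 and 791 without its control replicates 1 and 3 and 859 without Tak-1 control replicate 2. For phosphate the 3 mutants gave 410, 205 and 294 without Tak-1 control replicate 2, 431, 254 and 350 without Tak-1 starved replicate 1, 1524, 1197 and 1363 without replicate 2, which lay apart from its group, and 466, 221 and 360 without replicate 3. Phosphate also gave 497 and 468 in Mpcsd-2 without its control replicates 1 and 3, 356, 374, 332 and 349 in Mperf20-21 without its control and starved replicates 2 and 3, and 386, 301 and 422 in Mphd9-14 without its control replicate 1 and starved replicates 2 and 3. Sucrose in Mpcsd-2 gave 189 without control replicate 1 of either genotype, 174 without its control replicate 3 or Tak-1 control replicate 2, 205 without Tak-1 starved replicate 1 and 589 without its starved replicate 3. In Mperf20-21 it gave 77, 20 and 54 without its control replicate 2 and starved replicates 1 and 2, 63 and 95 without Tak-1 control replicates 1 and 2, and 95 and 89 without Tak-1 starved replicates 1 and 3. In Mphd9-14 it gave 191 and 197 without its control replicate 3 and Tak-1 control replicate 1. In Mphd9-14, 1 of the 5 oil body genes responded higher to phosphate starvation (camera adjusted p = 0.0283, and adjusted p = 0.215 with an estimated correlation). The mutant set held no Tak-1, so the experiment effect was neither measured nor told from genotype here. Against the control-condition set, controls of 1 genotype differed in 7789 (Mpcsd-2), 7081 (Mperf20-21), 6008 (Mphd9-14) and 7842 (time-course Tak-1) of 13150 genes.

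**Figure D4:**
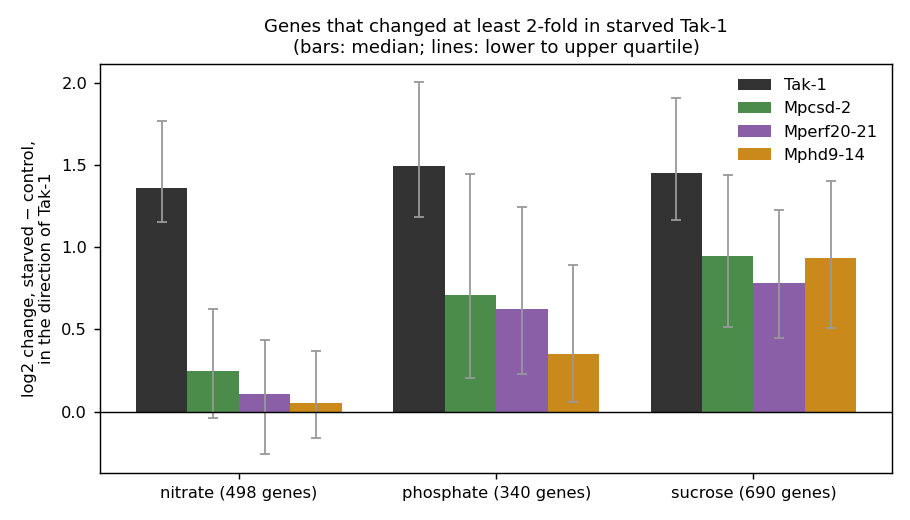
Bars are the median log2 changes, in the wild-type direction, of genes changed at least 2-fold in Tak-1 by each starvation (498, 340 and 690 genes). They are given for Tak-1 and the 3 mutants of another experiment, with lines from lower to upper quartile over genes. Nitrate medians are 1.36 in Tak-1 and 0.25, 0.11 and 0.05 in the mutants.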

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

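All tests of explanations in this part were chosen after the results they bear on were seen, as were the splits drawn without restriction; the balanced splits were added after those draws and their predictions were written before their own results. The 9 tests of a difference in starvation response between a mutant and Tak-1 each called genes. For nitrate, 1402 genes differed in Mpcsd-2, 1893 in Mperf20-21 and 1934 in Mphd9-14. For phosphate the numbers were 855, 607 and 642, and for sucrose 353, 159 and 340. Leaving out 1 library gave 791 to 1791, 1296 to 1825 and 1438 to 1925 for nitrate, 410 to 1524, 205 to 1197 and 294 to 1363 for phosphate (lowest without Tak-1 control replicate 2, highest without Tak-1 starved replicate 2, which lay apart from its group), and 174 to 589, 20 to 153 and 191 to 303 for sucrose, with the libraries named beside the counts above.

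The first pattern is the small response of the mutants to nitrate starvation. Too little power in the mutant libraries would lower the number of calls and leave the size of the changes, yet the highest median over the mutants was 0.25 where Tak-1 had 1.36, and the SE was 0.119 against 0.101. The nitrate responses of the mutants correlated with that of Tak-1 at 0.119, -0.036 and -0.104 across genes, which are not independent replicates. A role of the 3 genes in the nitrate response and a weaker depletion in the mutant experiment may each give this pattern, and they cannot be told apart without starved Tak-1 in that experiment.

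The second pattern is the distance of resupplied K. nitens from control. The lowest ratio of the 6 h to the 72 h median change over the nutrients was 1.01. Time since the control harvest remains open, as its day is not given. A few genes taking most of the counts would need their share to differ widely, and the share of the 10 most counted genes ranged over 1.48 percentage points. A batch shared by the 27 resupply libraries remains open, since all 27 lay beyond the others on the first principal component. A lasting response to fresh medium was not tested.

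The third pattern is the difference from Tak-1 shared by the 3 mutants under control conditions. Chance deviations of the shared Tak-1 libraries would give a covariance of at most 0.0197, and the lowest observed was 0.253. Against a property of that set alone, of the 2789 genes called the same way in all 3 mutants, 907, 1266 and 1305 were called that way across experiments in Mpcsd-2, Mperf20-21 and Mphd9-14 (independent 725, 561 and 608) and 668, 242 and 285 the opposite way. It remains open all the same, since that comparison carries the experiment as well, and the differences from Tak-1 correlated between experiments at 0.157, 0.052 and 0.137 across genes (0.217 to 0.288 between mutants). The 3 mutations may share targets, or the Tak-1 cultures of that set may differ from the mutants in some other way.

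Splits were run in fits of the compared groups alone, so real counts differ from those over all groups. For comparisons of 3 libraries with 3 there are 10 splits, too few for a share under 0.05. The real split was the highest, 1 of 10, in each, and the highest other split called 0 genes. These splits mix the groups as well: the common dispersion was at least 1.61 times the real one in M. polymorpha, 3.33 in K. nitens and 6.37 for the mutants under control conditions, so the 0 there may partly follow from the mixing. For starved mutants the lowest ratio was 0.744, so a higher dispersion does not account for the 0 in all of them. The real values were 1775 to 6719 over 15 M. polymorpha comparisons, 4615 to 9326 over 15 K. nitens comparisons, 4883 to 6903 for the 3 mutants under control conditions and 30 to 3283 for 8 starvations of mutants. For the interactions 33 splits were drawn. The real split alone was as large (1 of 33) for Mperf20-21 with nitrate (real 2630, highest other 1374) and phosphate (1005 and 272), and for Mphd9-14 with nitrate (3211 and 1975) and phosphate (1453 and 415). Chance was not excluded for Mpcsd-2 with nitrate (2 splits, 984 and 1423), phosphate (3 splits, 547 and 3435) and sucrose (2 splits, 20 and 61), nor for Mphd9-14 with sucrose (2 splits, 618 and 1931). The split with 3435 genes, several times the real 547, points to a structure of the samples: unequal exchange between conditions mixes the difference between the experiments into the contrast. With the same number exchanged in both conditions, the highest other of 33 splits called 0 genes in all 8 interactions. Every exchange puts libraries of both experiments into 1 group, and the common dispersion of the other splits was at least 2.97 times the real one, or 5.45 times with equal exchange, which lowers their calls; this was examined after the splits were seen. So neither set of splits excludes chance for any of the 8. Sucrose in Mperf20-21 had 2 starved libraries and was not split.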

How the results depend on the processing

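The alternatives reported here were planned, except the fit of the 4 groups of an interaction alone and the lists without phosphate-starved replicate 2, chosen after seeing the data. Of the tested counts of genes, DESeq2 moved 1 of 57 by more than 1.5 times, median-ratio factors 0 of 51, no filter 0 of 51, the stricter filter 2 of 51, the replicate block 0 of 41, a fit of the compared groups alone 8 of 42, the 4 groups alone 7 of 9 and leaving out 1 library 77 of 412. The starved Mphd9-14 count for nitrate (160) was 250 with DESeq2 and 84 with the stricter filter, and for phosphate (303) 180 with the stricter filter, which tests fewer genes. With the compared groups alone, 72 h of resupply against control gave 2273 for nitrate and 1775 for phosphate in M. polymorpha. The same fit gave 30, 542 and 249 for Mpcsd-2 without nitrate, phosphate and sucrose, 906 for Mperf20-21 without phosphate, and 572 and 707 for Mphd9-14 without nitrate and phosphate; the cause was not tested. The 4 groups alone gave interactions of 547 (phosphate) and 20 (sucrose) in Mpcsd-2, 1005 and 371 in Mperf20-21, and 3211 (nitrate), 1453 and 618 in Mphd9-14. Requiring a 2-fold change in both comparisons left 243, 263 and 143 shared genes for nitrate with phosphate, nitrate with sucrose and phosphate with sucrose in M. polymorpha and 314, 882 and 471 in K. nitens, by construction. With an estimated correlation camera called 1 list test in starvation, 2 in resupply, 1 after recovery, 0 in mutants under control conditions, 15 in starved mutants and 7 in interactions, against 17, 84, 19, 15, 97 and 90 with the preset; fry, which does not compare a list with other genes, called 54, 219 and 82 in starvation, resupply and mutants.

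Leaving out 1 library in turn gave these ranges; some omissions lowered the number of calls and others raised it, and the cause was not tested. M. polymorpha without phosphate: 2137 (without control replicate 2) to 3556. At 72 h against control: nitrate 509 to 851, with all 6 omissions moving the count, phosphate 342 to 702 (358 and 388 without control replicates 1 and 3, 557 and 342 without resupplied replicates 1 and 3) and sucrose 1147 to 1857 (1150 and 1305 without control replicates 1 and 3, 1147 without resupplied replicate 2). Mpcsd-2: nitrate 98 to 467 (151 without control replicate 3, 98 and 467 without starved replicates 1 and 3), phosphate 626 (without starved replicate 2) to 1070, sucrose 1845 (without starved replicate 2) to 4143. Mperf20-21: nitrate 164 (without starved replicate 1) to 425, with 267, 245 and 240 without the control replicates; phosphate 372 (without control replicate 1) to 450; sucrose 793 (without starved replicate 1) to 1674, with 1164 without starved replicate 2 and 1331 without control replicate 3. With 1 starved library left there, its spread was taken from the other groups. Mphd9-14: nitrate 45 (without control replicate 2) to 110, with 84, 76, 64 and 75 without control replicates 1 and 3 and starved replicates 1 and 3; phosphate 163 (without starved replicate 2) to 261, with 186, 176 and 185 without the control replicates; sucrose 1800 (without starved replicate 2) to 3225. Interactions of Mpcsd-2: nitrate 791 to 1791 (884 and 791 without its control replicates 1 and 3, 859 without Tak-1 control replicate 2), phosphate 410 (without Tak-1 control replicate 2) to 1524 (without Tak-1 starved replicate 2), sucrose 174 (without its control replicate 3) to 589 (without its starved replicate 3). Interactions of Mperf20-21: phosphate 205 (without Tak-1 control replicate 2) to 1197 (without Tak-1 starved replicate 2), sucrose 20 (without its starved replicate 1) to 153. Interactions of Mphd9-14: phosphate 294 (without Tak-1 control replicate 2) to 1363 (without Tak-1 starved replicate 2), sucrose 191 and 197 (without its control replicate 3 and Tak-1 control replicate 1) to 303. Of the genes named in the report, 4 values near 0 that were not called changed sign: MpERF20 without nitrate (-0.52 to 0.19) and phosphate (-0.21 to 0.22, and 0 with the stricter filter), and the phosphate interaction of MpPTB8 in Mperf20-21 (-0.55 to 0.12) and Mphd9-14 (-0.57 to 0.1), positive without Tak-1 starved replicate 2. The genes shared by phosphate and sucrose starvation numbered 943 (without control replicate 2) to 1594.

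With a replicate block, nitrate starvation of M. polymorpha called 4140 genes in place of 4261, and the block changed no count by more than 1.5 times. Same-numbered libraries correlated over 0.1 in every pair in 0 of 32 comparisons, and in 1 each library correlated best with its own number, so the numbers were not taken as pairs. No paired analysis was run for nitrate and phosphate in K. nitens, as those column numbers were not tied to samples. The share of higher calls moved by over 10 percentage points for Mperf20-21 without phosphate (501 higher and 101 lower; 662 and 244 with the compared groups alone), Mphd9-14 without nitrate (141 and 19; 413 and 159), and the interactions of Mperf20-21 with phosphate (246 and 361; 452 and 420 with DESeq2) and sucrose (26 and 133; 68 and 170 with DESeq2, 98 and 273 with the 4 groups alone), of Mpcsd-2 with sucrose (103 and 250; 3 and 17 with the 4 groups alone) and of Mphd9-14 with sucrose (118 and 222; 230 and 240 with DESeq2, 150 and 175 with median-ratio factors, 129 and 154 without a filter). Scaling by library size alone shifted the median of all genes by up to 0.555 in K. nitens, where phosphate at 72 h against control moved farthest, by 0.11 at 6 h of sucrose in M. polymorpha, and by -0.141, -0.114 and -0.104 for sucrose in Mpcsd-2 and Mphd9-14 and for Mpcsd-2 against Tak-1; with TMM the medians lay between -0.026 and 0.074. With 16878159 to 38992957 counts per library, depth limits genes near 0 counts, for which intervals are given.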

Other observations

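Several gene families moved in both directions under starvation, and some lists here passed fry but none camera. Counts are members that rose and fell without nitrate, phosphate and sucrose in turn. Of 33 cupins, seed storage protein relatives, 6, 6 and 4 rose and 7, 5 and 5 fell. Of 42 LEA genes 6, 3 and 6 rose and 1, 2 and 5 fell. Of 70 peroxidases 10, 5 and 10 rose and 3, 4 and 8 fell, and of 30 polyphenol oxidases 5, 5 and 5 rose and 1, 4 and 6 fell. Of 36 dirigent proteins 4, 3 and 4 rose and 3, 3 and 10 fell. Of 32 glutathione S-transferases 3, 2 and 3 rose and 6, 4 and 12 fell. Of 66 phenylpropanoid and flavonoid genes 9, 8 and 9 rose and 18, 11 and 16 fell; MpF3H fell by 0.67 ± 0.09 without nitrate (adjusted p = 1.49e-06) and fell by 1.2 ± 0.09 without sucrose (adjusted p = 7.17e-11). Of 13 shikimate pathway genes 0, 0 and 1 rose and 6, 4 and 6 fell. Of 15 terpene synthases 3, 2 and 1 rose and 2, 1 and 5 fell, of 11 lipoxygenases 3, 4 and 2 rose and 1, 2 and 1 fell, and of 19 CYP829 cytochromes 2, 4 and 4 rose and 2, 2 and 5 fell. Storage lipid droplet genes rose in 2, 3 and 2 of 7 cases and fell in 0. MpOLEOSIN, an oil droplet coat protein gene, rose by 1.48 ± 0.4 without phosphate (adjusted p = 0.0064).

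Of wall and membrane lists too, some passed fry and none camera. Of 99 glycoside hydrolases and other carbohydrate-active enzymes 17, 11 and 18 rose and 9, 14 and 22 fell. Of 80 glycosyltransferases 25, 12 and 22 rose and 7, 12 and 8 fell. Of 30 expansins 1, 1 and 3 rose and 6, 4 and 11 fell. Of 73 receptor-like kinases 18, 9 and 23 rose and 14, 8 and 19 fell. Of 15 proton pumps 1, 2 and 2 rose and 4, 4 and 5 fell. Of 5 aquaporins 0, 1 and 1 rose and 2, 2 and 2 fell, of 13 lipid transfer proteins 3, 1 and 2 rose and 4, 2 and 6 fell, and of 15 pathogenesis-related genes 2, 2 and 4 rose and 2, 1 and 3 fell. Of 5 HSP90 genes 1, 0 and 0 rose and 0, 0 and 1 fell, with the same counts adjusted over the list alone. Among regulators, of 37 bHLH genes 8, 6 and 9 rose and 5, 2 and 5 fell. Of 34 MYB genes 9, 9 and 7 rose and 7, 5 and 7 fell. Of 16 homeodomain genes 4, 2 and 2 rose and 4, 3 and 4 fell. On the word list of the transcription factor families of the study 2, 0 and 1 of 5 rose and 1, 1 and 2 fell, also adjusted over the list alone. As markers of other cell types, of 5 genes of oil body cells 0 rose and 2, 1 and 3 fell, and of 5 genes of the antheridium and sperm 1, 0 and 2 rose and 0 fell; MpDUO1, a regulator of male germ cells, rose by 1.18 ± 0.36 without sucrose (adjusted p = 0.011, at most 0.0512 without control replicate 1 or starved replicate 3).

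In later comparisons some lists had a median, a mean and a test of different sign. Pathogenesis-related genes in Mperf20-21 without phosphate had a median of -0.01, a mean of 0.216 and a test toward higher (camera adjusted p = 0.0403, and adjusted p = 0.22 with an estimated correlation). For the interactions with sucrose, dirigent proteins in Mperf20-21 had -0.021 and 0.421 (camera adjusted p = 0.0383, toward higher, and 0.623 with an estimated correlation) and pathogenesis-related genes in Mphd9-14 had -0.059 and 0.392 (camera adjusted p = 0.0258, toward higher, and 0.234 with an estimated correlation). After 72 h of resupply dirigent proteins were higher than control in 2, 3 and 5 of 36 cases and lower in 0 after nitrate, phosphate and sucrose, with camera adjusted p = 0.00436, 0.000493 and 0.0328, and adjusted p = 0.338, 0.213 and 0.526 with an estimated correlation. No hypothesis beyond those weighed above was tested.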
